A study of Bifidobacterium breve UCC2003 with 4 samples.

How the data were processed

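RNA of Bifidobacterium breve UCC2003, a human gut commensal, was measured on 4 2-colour Agilent DNA microarrays. On each array the Cy5 channel held RNA of a culture with bile and the Cy3 channel RNA of a control culture in MRS medium, per the labels. No dyes were swapped, and the labels do not say whether arrays shared a control culture. The 4 conditions were growth with 0.3% ox-gall to an OD600 of 0.5, growth with 0.06% cholic acid to an OD600 of 0.5, and 1 h of exposure at an OD600 of 1.0 to 0.06% cholic acid or to 0.15% ox-gall. Ox-gall is dried ox bile, a mixture of bile constituents, and cholic acid is a single free bile acid. The exposure controls received the same volume of sterile water. The growth text of both exposure samples also lists 0.06% cholic acid in the medium before the exposure, which their source names do not, so whether these cultures met cholic acid earlier is unclear. Each condition had 1 array and the series describes single experiments, so no comparison within a condition has a replicate check. The arrays' number limits the precision.

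The deposited intensity values are the mean brightness of each spot and the median of its local background in both channels, quantified with Feature Extraction version 9.5, per the labels. The log10 values deposited for the same spots are Feature Extraction's own ratio of processed Cy5 to processed Cy3 signal, per the file headers, after its background subtraction, detrending and dye normalization. The authors' series table held the same log10 ratios for all 10807 spots of each array, to within 1.6e-07 on the log2 scale, so its scale, centring and direction are known. Its median over spots was 0 on every array. The processed log10 ratio of 2.85% of the spots of the ox-gall growth array did not equal the log10 ratio of the 2 processed signals, to within 0.0001.

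Of the 10807 spots, 10263 were not control spots. They carried 5664 probes of 60 nt for 1888 features, 3 probes per feature, and 81.2% of the probes had 2 spots. Of the features, 1843 were genes with a Bbr locus tag and 45 had other names (tRNAs, 16S rRNA, plasmid genes, spike-ins). The 3 probes of a gene started within 60 nt of each other for 74.0% of the genes, so most probes of a gene overlap and their spread is a technical one. Background was corrected with normexp (offset 50) on mean signal and background median, and each array was normalized by loess (span 0.3, 4 iterations) with control spots and outlier-flagged spots at weight 0. Outlier-flagged spots were then left out (6 to 37 per array) and saturated spots were kept. Log2 ratios of Cy5 over Cy3 were averaged over spots, then over probes. R 4.3.3 and limma 3.58.1 were used.

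Signals stood well above background in 94.1% to 98.4% of the Cy3 spots and 96.0% to 98.6% of the Cy5 spots. Saturated spots were at most 0.38% of a channel. None of the counted features was below the well-above-background flag in all its spots in either channel (0 on each array). None was saturated in all its spots (0 on each array). So no counted fold rests on dim spots alone or on saturated spots alone. A feature with only some dim or saturated spots was not singled out, so its fold may still be a lower limit. The median log2 ratio before normalization was -1.61 for ox-gall growth, -0.60 for cholic acid growth, -1.43 for cholic acid exposure and -0.87 for ox-gall exposure. Normalization removes this offset, so a shift of all transcripts together cannot be seen. The SD between 2 spots of one probe was 0.05 to 0.07 on the log2 scale.

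With 1 array per condition no gene was tested within a condition. A gene was counted as higher or lower when its mean log2 ratio was at least 1 in size (2-fold), at least 2 probes were measured and at least 80% of them lay on that side of 0. The error given is the SD over the gene's probes on that array. Over the 4 arrays, limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05 over 1843 genes) tested the average log2 ratio with 3 residual degrees of freedom. An additive model of mode (exposure minus growth) and compound (ox-gall minus cholic acid) had 1 residual degree of freedom. In the average the 4 conditions stand in for replicates, so p-values measure the spread between conditions, and a dye effect of a gene cannot be told from a bile effect. Both ox-gall arrays lay on slide 1 and both cholic acid arrays on slide 2, so slide and compound cannot be told apart, and the compound term of the model is also the slide block for mode.

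Runs were at least 3 genes with consecutive locus tags counted in the same direction on an array. A gene list was described on each array by its median and the percentile of that median among 10000 random lists matched on brightness, and over the arrays with camera (preset correlation 0.01, and an estimated one), adjusted over the 3 coefficients because only 1 list could be used. The tests, the 25 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The reference table given (2016 genes) describes another strain of B. breve and matched 0 of the 1843 locus tags, and the files give no gene symbols. So 24 of the 25 lists, bile salt hydrolase among them, had no member that could be matched, and only the list of 9 transporter genes named in the study could be used. The study had chosen those 9 genes on these same arrays, so fixing this list beforehand does not make it independent of the data. The rule for named genes took the 10 highest and 8 lowest genes of each array, the 4 smallest p-values per direction of each limma fit where fewer than 4 genes pass, all 9 transporter genes and the 3 longest runs. Because the tags carry no names here, at most 2 genes per direction are printed for each array or fit beside the transporter genes, and runs are given by their first and last gene. Other genes were named after their values were seen where a count was small. Bbr_0418 and Bbr_0527, Bbr_0419 and Bbr_0528, and Bbr_0502 and Bbr_0503 share probe sequences, so their values are uncertain.

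The calculations were tested on simulated data of 1843 genes with 200 changed genes. For the average over the 4 arrays, 71.8% of genes changed by a log2 value of 1 and 92.5% of those changed by 2 were recovered (10 simulated sets). For exposure against growth 1.3%, 9.4% and 70.9% of genes changed by 1, 2 and 4 were recovered, and for ox-gall against cholic acid 1.5%, 5.7% and 73.6%. False calls were 5.3%, 9.7% and 5.0% of the calls of the 3 comparisons. These figures hold for genes with an equal shift on all arrays concerned and a spread unrelated to that shift. They do not carry over to genes whose response varied between conditions. The rule of size recovered 100% of genes changed by 2 on 1 simulated array and 47.8% of those changed by exactly 1. Alternatives were a 3-fold threshold, median centring, no background subtraction, the deposited ratios, a filter on dim probes, the median over probes, no minimum agreement of probes, scaling between arrays, eBayes with trend and robust, models without the other term, leaving out each array, and slide as a block. Array weights and the rotation test fry were chosen after seeing the data.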

Results

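The transcriptome of Bifidobacterium breve UCC2003, a gut bacterium that meets bile in its host, was compared between cultures with bile and cultures without it. Growth in the continuous presence of 0.3% ox-gall or 0.06% cholic acid was set beside a 1 h exposure to 0.15% ox-gall or 0.06% cholic acid. The study asked which genes the bacterium uses to protect itself from bile. Each of the 4 conditions was measured on 1 array of 1843 genes, as the log2 ratio of the bile culture over the control on the same array. There were no replicates, so each value is given with its SD over the 3 probes of the gene, a spread within the array. The median signal was 685 to 1044 in the control channel and 312 to 585 in the bile channel, over background medians of 38 to 47.

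Growth with 0.3% ox-gall asks what differs in cells dividing in MRS medium with dried ox bile. It gave 293 genes at least 2-fold higher and 264 at least 2-fold lower than in the control, 30.2% of those measured. The highest was Bbr_0625 at a log2 ratio of 4.60 ± 0.13, or 24.2-fold, followed by Bbr_0876 at 4.45 ± 0.035. The lowest were the neighbours Bbr_1582 at -4.74 ± 0.050 and Bbr_1581 at -4.54 ± 0.11. All 9 transporter genes that the study took up were counted as higher here, from 1.06 for Bbr_1756 to 3.66 for Bbr_0838. Bbr_1756 fell short of 2-fold with median centring (0.86) and with the deposited processed ratios (0.97), which leaves 8. The longest run comprised 17 consecutive genes, Bbr_1626 to Bbr_1642, all lower with log2 ratios of -1.97 to -1.19. Next came 8 genes from Bbr_1898 to Bbr_1905, higher by 1.32 to 2.22, and 7 genes from Bbr_1473 to Bbr_1479, lower with -2.57 to -1.09. The difference rests on 1 pair of cultures and was not tested. The count was 203 at a 3-fold threshold and 779 with the deposited processed ratios, and with median centring 272 genes were higher and 335 lower.

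Growth with 0.06% cholic acid gave fewer genes past the same size, 81 higher and 40 lower, or 6.57% of those measured. Bbr_0838, a transporter gene of the major facilitator superfamily, was the highest at 4.14 ± 0.30, a 17.6-fold ratio. Bbr_1865 followed at 2.98 ± 0.021. The lowest genes were Bbr_1479 at -2.09 ± 0.041 and Bbr_1582 at -2.05 ± 0.013. Of the 9 transporter genes 5 were counted as higher, the ABC-type pairs Bbr_0406 with Bbr_0407 and Bbr_1804 with Bbr_1805, and Bbr_0838. With the deposited processed ratios Bbr_0832 (1.46) and Bbr_1756 (1.06) were counted too and Bbr_1804 (0.96) was not, which gives 6, and at 3-fold 3 were counted. The longest runs held 4 genes each. Bbr_0106 to Bbr_0109 and Bbr_1890 to Bbr_1893 were higher, with log2 ratios of 1.54 to 2.09 and 1.43 to 1.60, while Bbr_0973 to Bbr_0976 and Bbr_1476 to Bbr_1479 were lower. No gene was tested. The count was 29 at a 3-fold threshold and 223 with the deposited processed ratios.

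One hour of exposure to 0.06% cholic acid, the same dose given briefly to denser cultures, gave 177 genes at least 2-fold higher and 122 lower, 16.2% of those measured. Bbr_0838 was again the highest at 4.82 ± 1.01, or 28.2-fold. Bbr_0107 followed at 3.58 ± 0.18 (4.29 with the deposited processed ratios), inside the run Bbr_0106 to Bbr_0109, whose 4 genes were higher by 2.55 to 3.58. The lowest genes were Bbr_0925 at -3.25 ± 0.034 and Bbr_1479 at -3.20 ± 0.053. The longest run held 7 lower genes, Bbr_0973 to Bbr_0979, with log2 ratios of -2.83 to -1.15. Runs of 5 genes followed, Bbr_1475 to Bbr_1479 lower and Bbr_1890 to Bbr_1894 higher. Of the 9 transporter genes 6 were counted as higher, the 5 of cholic acid growth and Bbr_1756. With the deposited processed ratios Bbr_0832 (1.69) and Bbr_1826 (1.05) were counted too, which gives 8. No gene was tested. The count was 116 at a 3-fold threshold. The excess of higher genes was lost with median centring (160 higher and 156 lower) and with the deposited ratios (232 and 225, or 457 in all).

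One hour of exposure to 0.15% ox-gall gave 14 genes at least 2-fold higher and 20 lower, 1.85% of those measured. Bbr_0838 was the highest at 3.61 ± 1.42, or 12.2-fold, followed by Bbr_0733 at 3.26 ± 0.38. Their order depended on the setting, since with the deposited processed ratios Bbr_0733 was at 4.72 and Bbr_0838 at 4.23. The lowest genes were Bbr_1719 at -3.41 ± 0.076 (-4.14 with the deposited ratios) and Bbr_1721 at -2.75 ± 0.019. They belong to a run of 4 lower genes, Bbr_1719 to Bbr_1722, with log2 ratios of -3.41 to -2.39. The other run of this array, Bbr_1826 to Bbr_1828, was higher by 1.88 to 2.01 and includes an ABC-type transporter pair. Of the 9 transporter genes 5 were counted as higher, Bbr_0406, Bbr_0407, Bbr_0838, Bbr_1826 and Bbr_1827, and 3 at 3-fold. No gene was tested, and the labels leave unclear whether the exposed culture had also met 0.06% cholic acid before. The count was 11 at a 3-fold threshold and 53 with the deposited processed ratios.

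**Figure D1:**
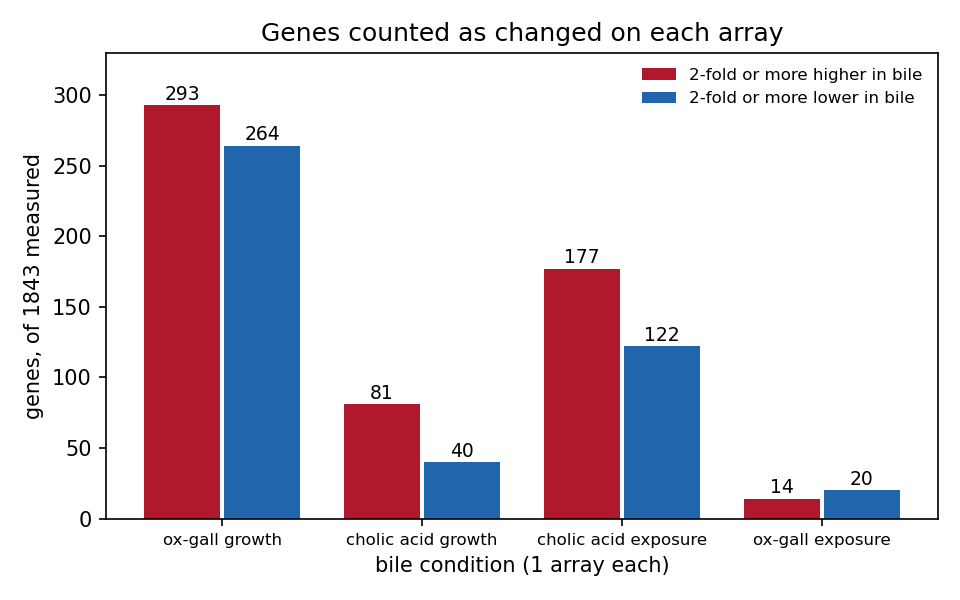
Number of genes (vertical axis, of 1843 measured) at least 2-fold higher (red) or lower (blue) in the bile culture than in its control, for the 4 conditions with 1 array each. Ox-gall growth has 293 higher and 264 lower genes and ox-gall exposure 14 and 20.

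The 9 transporter genes taken up by the study divide into 3 genes for major facilitator superfamily proteins (Bbr_0832, Bbr_0838 and Bbr_1756) and 6 for ABC-type transporters. These functions are background knowledge of the study and are not given in the files used here. The study chose these genes on the same arrays, so their direction is not independent evidence. Bbr_0838 had log2 ratios between 3.61 and 4.82 on the 4 arrays, and with the deposited processed ratios between 4.22 and 5.02. Its 3 probes lie far apart in the gene and differed, with the lowest at 2.01 and the highest at 4.70 on the ox-gall exposure array. The pair Bbr_0406 and Bbr_0407 was higher in all 4 conditions, from 1.33 for Bbr_0407 in ox-gall exposure to 2.89 for Bbr_0406 in ox-gall growth. Bbr_1804 was at 3.46 ± 0.025 in ox-gall growth, 1.16 ± 0.023 in cholic acid growth and 2.34 ± 0.049 in cholic acid exposure, but at -0.08 ± 0.042 in ox-gall exposure, and Bbr_1805 had a like profile. Bbr_1826 was at 2.85 ± 0.035 and 1.88 ± 0.048 in the ox-gall conditions and at 0.23 ± 0.024 and 0.73 ± 0.023 in those with cholic acid. Bbr_0832 reached 1.29 ± 0.081 in ox-gall growth and was between 0.49 and 0.96 elsewhere. With the deposited processed ratios it was at 1.99 in ox-gall growth, 1.46 and 1.69 in cholic acid growth and exposure, and 0.82 in ox-gall exposure. The list's median log2 ratio was 2.89, 1.099, 2.07 and 1.33 in ox-gall growth, cholic acid growth, cholic acid exposure and ox-gall exposure. Each of these medians lay above those of all 10000 random lists of the same brightness (percentile 100). A list chosen on the same arrays is favoured by that choice, so the percentile describes the list and tests nothing.

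**Figure D2:**
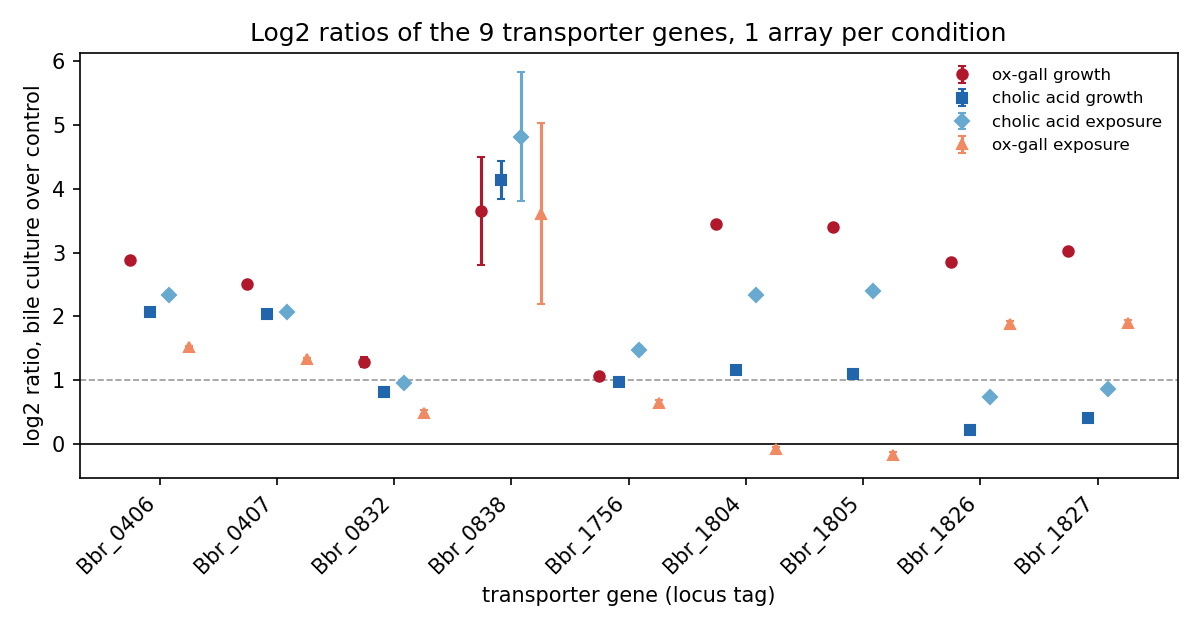
Log2 ratio of the bile culture over its control (vertical axis) for the 9 transporter genes (horizontal axis), with 1 point per array and bars of 1 SD over the 3 probes of the gene. The dashed line marks a 2-fold ratio. Bbr_0838 lies between 3.61 and 4.82 on the 4 arrays, while Bbr_1804 ranges from -0.08 to 3.46.

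The average over the 4 bile arrays asks which genes moved the same way in every condition. Bbr_0838 alone passed, with an average log2 ratio of 4.06 (SE 0.24), or 16.6-fold, higher on 4 of 4 arrays (limma, adjusted p = 0.0138). The next genes in p, Bbr_0407 at 1.99 (SE 0.21) and Bbr_0406 at 2.21 (SE 0.24), did not pass (limma, adjusted p = 0.0885 for both). Of the genes with lower values, Bbr_1887 averaged -1.13 (SE 0.14) and Bbr_1888 -1.17 (SE 0.15), and neither passed (limma, adjusted p = 0.0885 for both). Adjusted over the list alone, all 9 transporter genes were below 0.05 in limma, from 6.73e-05 to 0.0346, which is not independent evidence. As a list they stood above the other genes with a mean of 1.84 (camera, adjusted p = 7.02e-07 over the 3 coefficients tested). The call was lost with an estimated correlation of 0.478 (camera, adjusted p = 0.273). The study chose the list on these arrays, so neither value is independent evidence. At an unadjusted p under 0.05 limma gave 588 genes, 303 higher and 285 lower, where 92 would be expected by chance. That number is no baseline for a shared bile effect, since the arrays share their dye orientation and may share controls. The count of passing genes depended on the fit. It was 0 without ox-gall growth or without cholic acid growth, 127 without ox-gall exposure, 604 with slide as a block and 88 with the deposited processed ratios.

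By the rule of size, 4 genes were at least 2-fold higher and 4 at least 2-fold lower on all 4 arrays. The higher ones were Bbr_0015, Bbr_0406, Bbr_0407 and Bbr_0838, and the lower ones Bbr_1583, Bbr_1720, Bbr_1721 and Bbr_1722, named after their values were seen. Bbr_0015 ranged from 1.07 in ox-gall exposure to 3.60 in ox-gall growth. The 3 neighbours Bbr_1720 to Bbr_1722 were between -1.05 and -1.57 in both growth conditions and between -2.39 and -2.75 in ox-gall exposure. In cholic acid exposure Bbr_1720 and Bbr_1721 were at -1.13 and -1.15 and Bbr_1722 at -2.50. On 3 of the 4 arrays, 36 further genes were higher and 26 lower. Of the 1843 genes, 848 (46.0%) had 1 sign on all 4 arrays, against 12.5% for independent signs. That figure is no baseline for arrays without an effect, since the 4 share their dye orientation and may share controls. In all, 1154 genes were counted on none of the arrays.

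The comparison of growth with 1 h exposure gave no gene that passed (limma, 0 genes). At an unadjusted p under 0.05 there were 2 genes, where 92 would be expected by chance. The only residual of this fit is the interaction of mode and compound, so genes whose difference varied between compounds could hardly pass. The 0 is therefore no evidence that growth and exposure were alike. The lowest p values belonged to Bbr_0417 and Bbr_0562. Bbr_0417 was at 1.57 and 2.02 in ox-gall and cholic acid growth and at -0.11 and 0.66 in the exposures, a difference of -1.52 (SE 0.42; limma, adjusted p = 0.999). Bbr_0562 was at -1.93 and -0.83 in growth and at -0.54 and 0.29 in exposure, a difference of 1.26 (SE 0.42; limma, adjusted p = 0.999). Within the cholic acid slide 65 genes were at least 2-fold higher in exposure than in growth and 39 lower. Within the ox-gall slide these numbers were 250 and 279. Across genes, which are not independent replicates, the exposure minus growth differences of the compounds correlated at r = -0.463. The list of transporter genes had a median difference of -0.33 (camera, adjusted p = 0.0694 over the 3 coefficients tested, 0.0463 before adjustment). With an estimated correlation the adjusted p = 0.787 (camera). That estimate was 1, from a fit with 1 residual degree of freedom, so this p-value is a weak check of the shift. OD600 and the dose of ox-gall differed between the modes, and on simulated data this design recovered 9.4% of log2 differences of 2.

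The comparison of ox-gall with cholic acid, a mixture against 1 free bile acid, also gave no gene that passed (limma, 0 genes). At an unadjusted p under 0.05 there were 30 genes, again below the 92 expected by chance, and the fit has the same residual. The lowest p on the cholic acid side was that of Bbr_1865, at 2.98 and 2.90 with cholic acid and 1.07 and 0.45 with ox-gall, a difference of -2.18 (SE 0.44; limma, adjusted p = 1). Bbr_0107 followed, at 1.99 and 3.58 with cholic acid and 0.21 and 0.03 with ox-gall. On the ox-gall side Bbr_0087 was at 2.33 and 2.14 with ox-gall and 0.24 and 0.90 with cholic acid, a difference of 1.67 (SE 0.47; limma, adjusted p = 1). Bbr_0413 was at 0.45 and 0.30 with ox-gall and -0.83 and -1.37 with cholic acid. The transporter pair Bbr_1826 and Bbr_1827 differed by 1.89 (SE 0.55) and 1.83 (SE 0.57) towards ox-gall, without passing (limma, adjusted p = 1 for both, and 0.132 for both adjusted over the list alone). The list of transporter genes had a median difference of -0.06 and a mean of 0.24, opposite in sign (camera, adjusted p = 0.317). The doses were not matched, and each compound had its own slide, so the compounds cannot be told apart from the slides. With the deposited processed ratios 3 genes passed, and with eBayes trend and robust 7.

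Neighbouring genes were often counted together. Runs of 3 or more consecutive genes numbered 43 in ox-gall growth, 8 in cholic acid growth, 23 in cholic acid exposure and 2 in ox-gall exposure, and held 20.6% to 32.5% of the counted genes. At a 3-fold threshold there were 11, 1, 8 and 2 runs in that order, and with the deposited processed ratios 65, 10, 40 and 4. The run Bbr_1626 to Bbr_1642 had a median log2 ratio of -1.47 in ox-gall growth and of -0.18, 0.04 and 0.35 in cholic acid growth, cholic acid exposure and ox-gall exposure. The run Bbr_0106 to Bbr_0109 had medians of 1.78 and 3.14 with cholic acid and of 0.38 and 0.04 with ox-gall. Bbr_0973 to Bbr_0978 were lower in ox-gall growth with a median of -1.91, and had medians of -1.18 and -2.47 in cholic acid growth and exposure and -0.64 in ox-gall exposure. Bbr_1719 to Bbr_1722 had medians of -2.60 in ox-gall exposure and between -1.36 and -1.14 in the other conditions, but Bbr_1722 alone was as low in cholic acid exposure (-2.50) as in ox-gall exposure (-2.39).

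**Figure D3:**
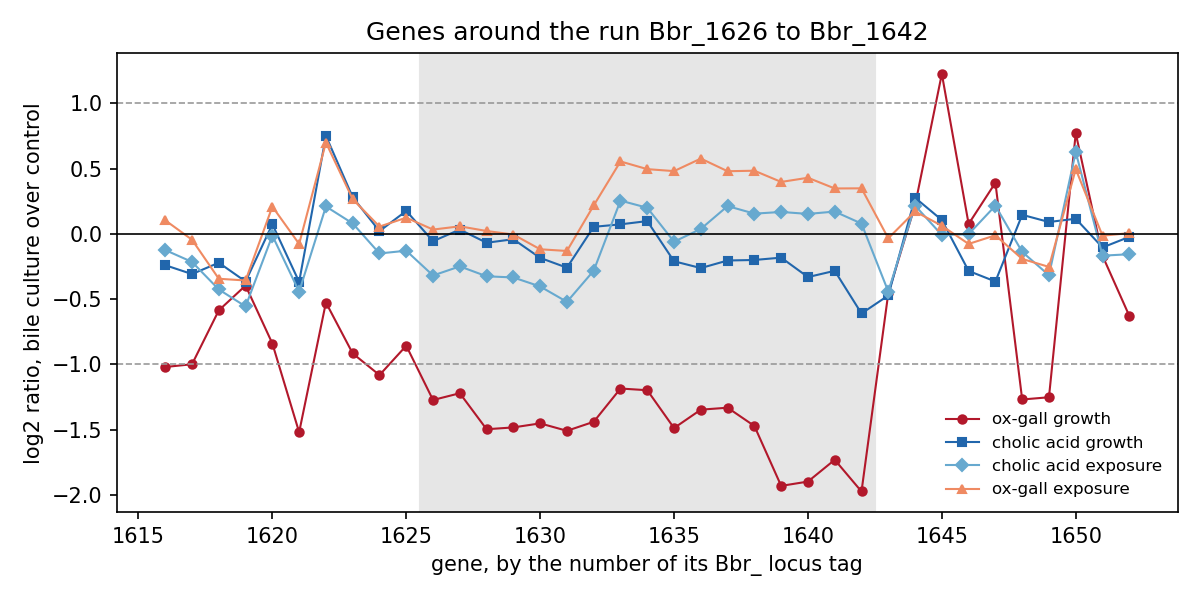
Log2 ratio of the bile culture over its control (vertical axis) for genes in the order of their locus tags (horizontal axis) around the run Bbr_1626 to Bbr_1642 (grey band), with 1 line per array. The dashed lines mark 2-fold ratios. The 17 genes lie between -1.97 and -1.19 in ox-gall growth.

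The overlap between arrays exceeded that of independent lists in every pair. Ox-gall growth and cholic acid exposure shared 115 higher and 72 lower genes, where 28.1 and 17.5 would be expected, and correlated at r = 0.712 (Spearman rho 0.702) across genes, which are not independent replicates. Both cholic acid arrays shared 60 higher and 35 lower genes against 7.78 and 2.65 expected, with r = 0.794 (rho 0.747). The arrays of ox-gall shared 10 higher and 10 lower genes against 2.23 and 2.86, with r = 0.338 (rho 0.289). The pairs of one mode gave r = 0.590 for growth and 0.439 for exposure. These overlaps were not tested pair by pair. The labels do not say whether the arrays of one mode shared a control culture, and part of the overlap beyond the expected numbers may come from shared controls and from the common dye orientation. The control channels of the 2 exposure arrays correlated at r = 0.994 across genes and those of the 2 growth arrays at 0.935, the lowest of the 6 pairs. The pairs of a growth with an exposure array lay between 0.941 and 0.981, with those of ox-gall growth at 0.941 and 0.953.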

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

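No tests were run on the values in this part, and no explanation was weighed for them. In all, 4 genes were at least 2-fold higher on one array and at least 2-fold lower on another. Ox-gall growth and cholic acid exposure had 1 such gene, where independent lists would give 44.7. The ox-gall arrays had 4 against 5.19 and the exposure arrays 3 against 2.85, so the number is not above that of independent lists by much in any of these pairs. Bbr_0787 and Bbr_1170 had values close to the threshold, and other settings are not given for the 4 genes. They were named after their values were seen, and the differences were not tested, since each condition has 1 array. The neighbours Bbr_0284 and Bbr_0285 were at 1.26 and 1.61 in ox-gall growth and at 1.72 and 1.58 in cholic acid exposure, but at -1.34 and -1.46 in ox-gall exposure. Bbr_0787 was at 1.02, 1.16 and 1.62 in ox-gall growth, cholic acid growth and cholic acid exposure and at -1.04 in ox-gall exposure. Bbr_1170 went the other way, with -1.06 in ox-gall growth, 1.01 in cholic acid exposure and 1.22 in ox-gall exposure. The SD over the 3 probes of these values was 0.11 at most.

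Features without a genomic locus tag, outside the comparisons of genes, also showed signal. The feature named rRNA16s had a log2 ratio of 1.51 ± 0.33 on the ox-gall growth array and of 0.15 to 0.22 on the other arrays. The feature pCIBb1-ORF7, a plasmid gene by its name, was at 1.70 ± 0.31 on the ox-gall growth array, 0.71 ± 0.053 in cholic acid growth, 0.65 ± 0.051 in cholic acid exposure and 0.26 ± 0.055 in ox-gall exposure. Other features named for the same plasmid stayed between 0.05 and 0.23 on the ox-gall growth array. The feature named CDS was lower, at -1.94 ± 0.024 in cholic acid exposure and -1.23 ± 0.004 in ox-gall exposure, and at -0.80 and -0.77 in ox-gall and cholic acid growth. Of the spike-in features, RNASPIKE3 was at 0.55 ± 0.10 and RNASPIKE4 at 0.50 ± 0.72 on the ox-gall growth array, where the others were between 0.04 and 0.29.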

How the results depend on the processing

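Array weights and fry were chosen after the data were seen. Each array pairs a bile culture with a control, but with 1 array per condition no replicates could be paired across conditions. Slides entered the models through the compound term for exposure against growth and as a block for the average. The totals of genes counted on each array stayed within 1.5 times under median centring, no background subtraction, the filter on dim probes, the median over probes and no minimum agreement of probes. Median centring turned the balance in ox-gall growth to 272 higher and 335 lower, with 479 genes counted the same way in both settings, and that in cholic acid exposure to 160 and 156. With a 3-fold threshold they were 203 in ox-gall growth, 29 in cholic acid growth, 116 in cholic acid exposure and 11 in ox-gall exposure, as a stricter threshold must lower them. With the deposited processed ratios, whether from the scanner files or the series table, they were 779 in ox-gall growth, 223 in cholic acid growth, 457 in cholic acid exposure and 53 in ox-gall exposure, and the cause was not tested. The 1 gene that passed for the average over the 4 arrays became 3 with median centring, 88 with the deposited ratios, 339 with scaling between arrays, 7 with trend and robust, 471 with array weights and 0 to 127 when an array was left out (0 without either growth array, 127 without ox-gall exposure). It became 604 with slide as a block, where the estimated correlation within slides was negative (-0.439), which narrows the standard error of an average. Bbr_0838 passed in all of these except without ox-gall growth (adjusted p = 0.116) and without cholic acid growth (adjusted p = 0.213, the highest of the range; the lowest was 6.43e-05 with the deposited ratios). Its average was 4.19 and 4.03 without those arrays, against 4.06 with all. Exposure against growth gave 0 genes under every alternative run, which says little about stability, since this design recovered 1.3% and 9.4% of simulated log2 differences of 1 and 2. Ox-gall against cholic acid gave 3 genes with the deposited ratios and 7 with trend and robust, and 0 otherwise. When an array was left out of these comparisons, the term for the other factor was dropped, as 3 arrays leave no residual for both, and the lone array of its arm was assumed to vary like the others. For the 9 transporter genes, before adjustment over the 3 coefficients, camera gave the average shift p = 0.091 with an estimated correlation and 4.35e-14 with slide as a block, and exposure against growth p = 0.615 with an estimated correlation; fry, which tests the genes against no change and not against other genes, gave 0.00459 and 0.757. These values come from limma's model and not from an exact test. They are not independent evidence, since the study chose the list on the same arrays. The counts that follow cover the 9 transporter genes, the highest and lowest genes printed for each array, and tRNA-Glu, and no other named gene. Where these features were counted on an array, 236 values under the 4 alternatives that differ held 0 changes of sign. Of these values, 104 moved by at least 1 SD over probes, 52 of them with the deposited ratios, and 6 were below 2-fold. The series table equals the scanner ratios and the filter on dim probes left all these values unchanged, so neither is included. The largest change was 1.46, for Bbr_0733 in ox-gall exposure with the deposited ratios. Where the same features were not counted on an array, 1 of 100 values changed sign, Bbr_0107 in ox-gall growth (-0.08 with median centring). At least 94.1% of the spots of each channel were flagged as well above background. That share does not show how far background handling moved the ratios of dim genes, which was not tested for dim genes alone.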

Other observations

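Of the tests below, the one on random noise of dim spots and both on the correlation between arrays were chosen after the result was seen. The intervals given for the first and second patterns are bootstraps over genes. They hold no spread between cultures or arrays, and they may be too narrow because neighbouring genes were correlated. Among features with names in place of locus tags, tRNA-Glu was at least 2-fold higher on all 4 arrays, with log2 ratios of 1.45 ± 0.025 in ox-gall growth, 2.07 ± 0.029 in cholic acid growth, 1.62 ± 0.025 in cholic acid exposure and 2.10 ± 0.029 in ox-gall exposure. tRNA-Gly was at 1.56 ± 0.032 in ox-gall growth and 1.55 ± 0.062 in cholic acid exposure. tRNA-Lys and tRNA-Leu were counted as higher in ox-gall growth, at 1.70 ± 0.040 and 1.02 ± 0.31, and tRNA-Gln in cholic acid growth at 1.30 ± 0.010. None of the 20 tRNA features was at least 2-fold lower (0 on each array). Their median log2 ratio was 0.22, 0.07, 0.16 and 0.08 in ox-gall growth, cholic acid growth, cholic acid exposure and ox-gall exposure, at percentiles 92.0, 79.6, 89.9 and 94.8 of random lists of genes of the same brightness. These features were chosen after their values were seen.

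The first pattern was the number of genes counted in ox-gall growth, 557 against 299 in cholic acid exposure, the next highest. Its control channel differed from the other controls, but 13.7% (bootstrap interval 9.6 to 17.6) of the mean signed ratio of its counted genes lay in that difference. This argues against an unusual control culture as the main source of these ratios. The same share was 21.2% in cholic acid growth, 0.2% in cholic acid exposure and 1.5% in ox-gall exposure. How many genes the control difference took past 2-fold was not determined. Among the 615 brightest genes it counted 1.68 times as many as the next array, with an interval of 1.45 to 1.94 that reached below the bound of 1.5 set beforehand. Of the 98 among the 614 dimmest genes that the first spots of their probes put at 2-fold or more, the second spots put 92.9% (87.8 to 98.0) there too. This argues against random noise between spots. Both spots carry the same probe and the same RNA, so a bias of dim genes on that array would repeat in both. Since the test on bright genes missed its bound, such a bias is not decided here. The higher dose of ox-gall and the longer contact with it, which the design gives, remain open and untested, as does chance between single cultures. Ox-gall growth also had the largest channel offset before normalization, at -1.61, and its part in the count was not tested.

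The second pattern was the correlation of gene ratios between arrays, which all have bile in Cy5. A dye effect of each gene, equal in size on all arrays, would give the 6 pairs about equal covariances. The highest was 5.43 times the lowest (interval 4.54 to 6.42), so an effect of equal size does not account for the whole. A dye effect whose size varied between arrays could also give unequal covariances, so these values do not decide on it. A control RNA shared within a mode would raise the pairs of one mode, but the covariance of ox-gall growth with cholic acid exposure exceeded both of theirs, by 0.246 (0.213 to 0.279) over the higher. Part of the correlation may still come from either, and the size of that part was not estimated. A response shared by ox-gall growth and cholic acid exposure is a hypothesis that these arrays cannot test against replicates. Both arrays also had the largest channel offsets before normalization, -1.61 and -1.43 against -0.60 and -0.87, and the part of these was not tested. By correlation the cholic acid arrays were the closest pair (r = 0.794 against 0.712).

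The third pattern was the runs of neighbouring genes. The number of genes in runs was 181, 28, 86 and 7 in ox-gall growth, cholic acid growth, cholic acid exposure and ox-gall exposure, above the highest numbers in 10000 random orders of the same calls (70, 8, 27 and 3) on all 4 arrays, so chance order is excluded. Spots of neighbouring genes lay no closer together than those of random genes (ratio of median distances 1, interval 0.99 to 1.01), which argues against a local fault of the array surface. The correlation of log2 ratios between genes was 0.36 to 0.43 at the next tag and 0.03 to 0.06 at a distance of 5 tags. Transcription of neighbouring genes as operons is consistent with this as a hypothesis, and was not tested, since no operon map was used here.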
